A study of Mus musculus with 18 samples.

How the data were processed

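RNA was measured in microglia sorted from mouse brain, in 18 libraries that fall into 6 groups of 3. The libraries were made with a bulk form of MARS-seq, a method that sequences tags from transcripts, per the labels' protocols. Of the groups, 4 came from 7-month-old mice: Gba-/-;Gbatg mice, which model chronic neuronopathic Gaucher disease, and their Gba+/-;Gbatg, Gba+/- and Gba+/+ controls. The other 2 came from 3-week-old wildtype mice injected from postnatal day 8 to day 21 with conduritol B-epoxide (CBE), an inhibitor of glucocerebrosidase, or with PBS. Nothing used here says whether each library came from 1 animal or from a pool, so the p-values measure the spread between these libraries.

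The authors deposited raw counts per gene in 3 tables, 1 each for the chronic, acute and age comparisons, per the file headers. The submitters' processing notes name cutadapt, HTSeq and the mouse build mm10. The aligner, the annotation, the strand setting and the treatment of molecular identifiers were not given in the sources used here. The tables list 9581, 9891 and 9729 genes, and in each table every gene has a count of at least 6 in some library. The same files hold log2 fold changes and adjusted p-values, which the authors deposited for their own comparisons, per the file headers. They were used only where the authors' deposited table is named. Another 48 columns of per-sample normalized and regularized values were not used.

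The tables were not counted alike. The 3 wildtype libraries stand in both the chronic and the age table, and over the 9354 genes in both, the chronic table holds 83.4%, 86.0% and 84.1% of the counts of the age table. Across genes the Spearman correlation of the 2 countings was 0.993, 0.992 and 0.993. The PBS libraries had identical counts for the 9403 genes listed in both the acute and the age table. Each comparison was therefore made inside 1 table. The test of chronic against acute effects used both tables, since each effect there is taken against controls counted in the same way.

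Total counts per library ran from 417961 to 1500769 in the chronic table, a range of 3.59 times. They ran from 1188808 to 2294244 in the acute table and from 779124 to 1799763 in the age table. Replicates of a group differed by more than sampling noise: chi-square per degree of freedom over genes was between 2.04 and 16.1 for the 18 pairs within groups. No 2 libraries were treated as 1.

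Genes were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM scaling, robust dispersions and the quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The chronic comparison set the 3 Gba-/-;Gbatg libraries against the unweighted mean of the 3 control genotypes in a fit of 12 libraries. The same fit gave the comparison with each control genotype and a joint test of differences between them. CBE was compared with PBS, and wildtype at 7 months with PBS at 3 weeks, in fits of 6 libraries. The difference between the chronic and acute effects came from a fit of all 18 libraries. Standard errors were derived from the log2 fold change and the p-value of the test. Levels are counts divided by the TMM-scaled library size of the tested genes (CPM), given as mean ± SD. Genes with near-identical copies, such as ribosomal proteins, H2 genes, Lilrb4a and members of the Oas family, can share tags, so their values are uncertain.

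Before the data were examined, 28 gene lists were fixed, of which 23 held tested genes in the chronic comparison, 25 in the acute and age comparisons and 24 in the difference. Cell type markers were among them. Markers of T and NK cells and of oligodendrocyte precursors and the mitochondrially encoded genes had no tested member in any of these. The lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and with an estimated one, and members were counted over all genes tested and adjusted over the list alone. The named genes were also fixed by rule: for the chronic, acute and age comparisons, the 8 genes per direction with the largest fold change among called genes with a mean of at least 10 CPM and no overlap between the libraries of both sides, up to 4 members of each list by p-value, and Gba. Predicted genes were skipped. For the difference, 5 genes per direction were taken, and 3 per direction for the single-control comparisons. The text names only part of these, and says where a gene was chosen after its values were seen. Coordinates are from GENCODE vM21, an annotation of the same build, and 96.6% of the genes tested in the chronic comparison were matched by symbol.

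The fits were tested on simulated data with 200 changed genes each. Rises and falls were equal in number, noise was independent between genes and no library stood apart. For the difference only the Gba-/-;Gbatg libraries were changed. The real data differ in these points, so the numbers may not carry over. With the dispersion and depth of the chronic comparison, 96 of 100 genes changed 4-fold and 74 of 100 changed 2-fold were found among 7048 genes, with 4 false calls. In the acute comparison these numbers were 92 and 45 among 7665 genes, with 8 false calls. In the age comparison they were 97 and 65 among 7727 genes, with 13 false calls. For the difference they were 79 and 15 among 7928 genes, with 3 false calls.

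Alternatives were DESeq2 1.42.0, RLE scaling, no count filter, leaving out each library, the replicate number as a block, a threshold of at least 2-fold, other sets of libraries in the fit and, chosen after seeing the data, scaling by library size alone and fits without doubted libraries or genes. The planned change of pseudocount did not apply, since counts were given.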

Results

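The series profiled microglia, the resident macrophages of the brain, in 2 mouse models of neuronopathic Gaucher disease, in which loss of the lysosomal enzyme glucocerebrosidase, encoded by Gba, lets glucosylceramide accumulate. The chronic model was examined at 7 months, after about 5.5 months of doxycycline, with 9 control libraries of 3 genotypes. The acute model was examined at 3 weeks, with 3 CBE and 3 PBS libraries. Total counts per library were between 417961 and 1500769 in the chronic table and between 1188808 and 2294244 in the acute table.

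Gba, on chromosome 3 from 89202928 to 89208966 on the plus strand, had 1, 4 and 4 counts in the 3 Gba-/-;Gbatg libraries, or 3.53 ± 2.45 CPM (SD, n = 3). The level was 244 ± 45.9 in Gba+/+, 133 ± 15.2 in Gba+/- and 168 ± 51.1 in Gba+/-;Gbatg libraries (SD, n = 3 each). The log2 fold change of the chronic model against the 3 control genotypes was -5.66 ± 0.31 (SE; edgeR adjusted p = 9.02e-13). The library labelled Gba+/-;Gbatg replicate 3 held 224.5 CPM (221 counts), above the other heterozygous libraries, which lay between 117.5 and 152, and within the range of the Gba+/+ libraries, 204 to 294. Which part of Gba is deleted was not given in the sources used here, so tags from a retained part would be counted. CBE acts on the enzyme, and Gba was higher in CBE than in PBS libraries, with 418 ± 111 against 241 ± 28.5 CPM (SD, n = 3 each) and a log2 fold change of 0.79 ± 0.21 (SE; edgeR adjusted p = 0.0235).

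**Figure D1:**
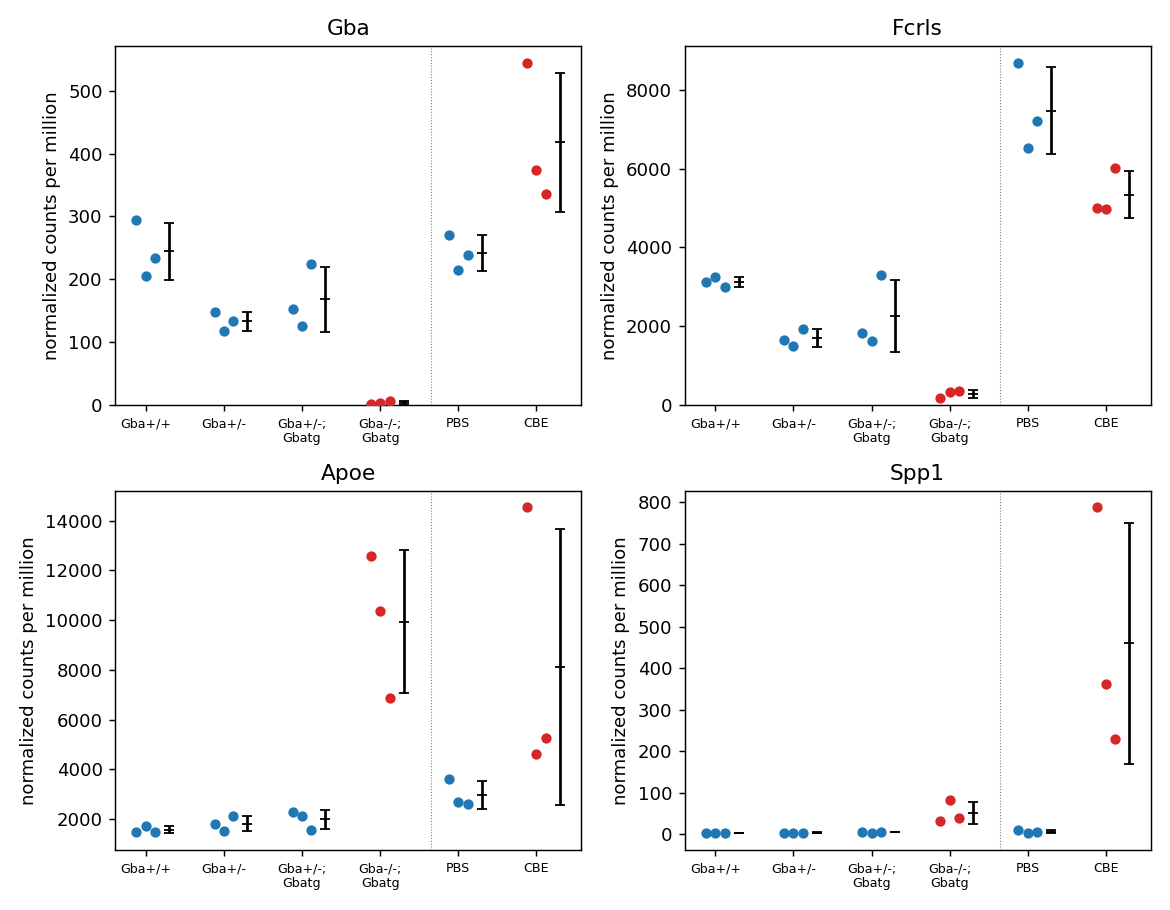
Normalized counts (CPM, linear axes) of Gba, Fcrls, Apoe and Spp1 in each library of the 6 groups, diseased groups in red, with the mean and SD of 3 libraries beside them; the dotted line parts the 7-month from the 3-week libraries, which were counted in different tables. Apoe and Spp1 lie above the controls in both diseased groups, and Gba is near 0 in the Gba-/-;Gbatg libraries alone.

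Which genes changed in microglia of the chronic model was asked against all 3 control genotypes. Apoe, a lipid-carrying protein, rose from 1791 ± 317 CPM in the 9 controls to 9940 ± 2863 in the 3 Gba-/-;Gbatg libraries (SD), a log2 fold change of 2.48 ± 0.14 (SE; edgeR adjusted p = 1.93e-12). Spp1, which encodes osteopontin, rose by 3.85 ± 0.32 on the log2 scale (adjusted p = 2.15e-09), from 3.60 ± 1.12 to 51.3 ± 27.0 CPM. The receptor Lilrb4a rose by 2.32 ± 0.29, the galectin Lgals3 by 1.99 ± 0.26, the cytokine Il1b by 1.97 ± 0.30, the receptor kinase Axl by 1.70 ± 0.24 and the cystatin Cst7 by 1.65 ± 0.18 (log2 ± SE). Fcrls and Fcrl1, Fc receptor-like genes, had log2 fold changes of -3.03 ± 0.27 and -2.91 ± 0.34 (SE) and lie 1.95 and 1.83 Mb from Gba on the same chromosome. In the 6 heterozygous control libraries they differed from Gba+/+ by -0.68 ± 0.23 and -0.70 ± 0.23 on the log2 scale (SE; edgeR adjusted p = 0.974 and 0.963).

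Of the 29 disease-associated microglia genes tested, 9 rose and none fell, and 14 rose when adjusted over the list alone. The list's median log2 fold change was 0.39, with a camera adjusted p of 3.72e-23, or adjusted p = 0.0017 with an estimated correlation. Of the 19 inflammatory cytokines and chemokines tested, 5 rose, among them Ccl4 by 1.27 ± 0.15, Cd83 by 0.63 ± 0.14 and Tnfaip3 by 0.70 ± 0.18 (log2 ± SE); 8 rose when adjusted over the list alone, with a camera adjusted p of 1.5e-06, or adjusted p = 0.0246 with an estimated correlation. Of the 25 homeostatic microglia genes, 5 fell and none rose, with 6 lower when adjusted over the list alone. Fcrls, which lies near Gba, was 1 of the 5, with -3.03 ± 0.27, and Olfml3 fell by 1.09 ± 0.15, Slc2a5 by 0.69 ± 0.14 and Bin1 by 0.61 ± 0.14 on the log2 scale (SE). The list had a median of -0.17 and a mean of -0.34 and was not tested without Fcrls. Its call was lost with an estimated correlation (adjusted p = 0.101). Ribosomal proteins rose in 26 of 72 cases, with 50 higher and 2 lower when adjusted over the list alone, among them Rps26 by 1.01 ± 0.13 (log2 ± SE), again with adjusted p = 0.101 with an estimated correlation. No member of the lists for interferon response (29 tested), MHC class I (14), MHC class II (8) or oxidative phosphorylation (36) was called over all genes by edgeR or by DESeq2; at an unadjusted p under 0.05 there were 8, 1, 1 and 9. Adjusted over the list alone, 1 MHC class II gene was higher, Cd74 with 0.51 ± 0.16 (log2 ± SE; edgeR adjusted p = 0.0755 over all genes), and none of the other 3 lists had a call. The oxidative phosphorylation list as a whole had a camera adjusted p of 0.0135 and a median of 0.20 on the log2 scale, with adjusted p = 0.724 with an estimated correlation. Of 13 glycolysis and hypoxia genes 2 fell, or 4 when adjusted over the list alone, Pfkl by 0.86 ± 0.18 and the lactate transporter Slc16a3 by 0.69 ± 0.14 on the log2 scale (SE), with adjusted p = 0.335 with an estimated correlation.

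Among the 56 lysosomal genes tested, 2 fell and none rose; these were Gba and Hexa, a subunit of a ganglioside-degrading enzyme, which fell by 0.52 ± 0.13 on the log2 scale (SE). The list had a median of 0.0066 and a mean of -0.085, with a camera adjusted p of 0.372 in the lower direction. This direction rested on Gba: without it, a step chosen after seeing the data, the mean was 0.016 and the camera adjusted p 0.993 in the higher direction. The median and mean of the MHC class I list and of the oligodendrocyte markers were also above 0 where camera gave the lower direction. Ugcg, which makes glucosylceramide, rose by 0.75 ± 0.21 (log2 ± SE, edgeR adjusted p = 0.04515). Of 15 lipid efflux and storage genes, 3 rose, including Abcg1, a cholesterol exporter, by 0.58 ± 0.17, and 1 fell, or 5 and 1 when adjusted over the list alone, with adjusted p = 0.0885 with an estimated correlation. Of 7 neutrophil markers, none rose and Csf3r fell by 0.57 ± 0.13 when all genes were considered, and 6 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0388; adjusted p = 0.567 with an estimated correlation). S100a9 had 73.1 ± 26.5 CPM in the diseased and 40.9 ± 58.5 in the control libraries (SD), a log2 fold change of 2.06 ± 0.61 (SE; edgeR adjusted p = 0.126). Within the controls it was 104 ± 66.1 in Gba+/-;Gbatg, 8.95 ± 12.4 in Gba+/- and 9.32 ± 9.94 in Gba+/+ (SD, n = 3 each). Of 36 hepatocyte genes tested, in a list written after the data were seen, 36 had positive values, and 2 rose in edgeR and 0 in DESeq2. The list had a median of 0.68 on the log2 scale and a camera adjusted p of 3.69e-08, or adjusted p = 0.227 with an estimated correlation. The summed level of the hepatocyte genes without Ttr was 3263 ± 578 CPM in the 3 diseased and 2346 ± 1121 in the 9 control libraries (SD).

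Of 26 glycosphingolipid and ceramide genes 1 rose and 2 fell, or 5 and 3 when adjusted over the list alone, with adjusted p = 0.576 with an estimated correlation. DESeq2 called 2 of the 26. Gba is a member, and the mean moved from -0.15 to 0.071 on the log2 scale without it. Of 23 complement and phagocytic receptor genes 2 rose, with 3 higher and 1 lower when adjusted over the list alone. None of 10 cholesterol synthesis, 9 cell cycle and 23 immediate early genes was called by edgeR or by DESeq2, with 1, 2 and 8 at an unadjusted p under 0.05; 2 immediate early genes were higher when adjusted over the list alone. Markers of monocytes, border-associated macrophages and B cells (1 gene tested each), astrocytes (2), oligodendrocytes (4) and endothelial cells and pericytes (2) were not called by either tool, with 1 oligodendrocyte marker at an unadjusted p under 0.05.

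The edgeR test called 235 of 7176 genes, 140 higher and 95 lower, and 57 of them differed at least 2-fold. The libraries of both sides did not overlap in 345 of the 7176 tested genes, or 4.81%, where chance gives 0.909% for 3 libraries against 9; 161 of the 235 were among them. Without Gba-/-;Gbatg replicate 1 the count was 123, and without replicate 3 it was 146.

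Against single control genotypes, 78 genes were called against Gba+/-;Gbatg, 139 against Gba+/- and 67 against Gba+/+ in edgeR. Apoe and Spp1 rose and Gba, Fcrls and Fcrl1 fell against each of the 3. The log2 fold change of Apoe was 2.32 ± 0.20, 2.46 ± 0.20 and 2.66 ± 0.20 (SE). In the authors' deposited table, 79, 114 and 98 genes had an adjusted p under 0.05 in these comparisons. The count against Gba+/-;Gbatg fell to 29 without its replicate 2 and to 29 without its replicate 3, to 36 without Gba-/-;Gbatg replicate 1 and to 48 without replicate 4. The count against Gba+/- fell to 46 without its replicate 2, 50 without its replicate 3, 73 without Gba-/-;Gbatg replicate 1 and 79 without replicate 3. That against Gba+/+ fell to 41 without its replicate 2 and 37 without its replicate 3.

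Between the control genotypes edgeR called 0 of 7176 genes in the joint test, with 308 at an unadjusted p under 0.05, and DESeq2 called 1. In the authors' deposited table, 3 genes had an adjusted p under 0.05 between Gba+/-;Gbatg and Gba+/-, 3 between Gba+/-;Gbatg and Gba+/+ and 6 between Gba+/- and Gba+/+. Gba had an adjusted p of 0.603 in edgeR. The gene DESeq2 called was Chil3, and in the pairwise comparison of Gba+/- with Gba+/+ both tools called Rps27l alone; these genes are named because of their small number, after their values were seen. Without Gba+/-;Gbatg replicate 1 or 3 edgeR called 3 genes, and without Gba+/- replicate 1 or 3 it called 1.

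In the acute model, genes of the type I interferon response rose together: 34 of the 35 tested, with a median log2 fold change of 3.98. Oas2, an antiviral RNA sensor, went from 1.08 ± 0.46 to 120 ± 17.2 CPM (SD, n = 3 each), a log2 fold change of 6.74 ± 0.33 (SE; edgeR adjusted p = 1.75e-07), and Phf11b rose by 3.87 ± 0.26. The camera adjusted p of this list was 1.16e-87, or adjusted p = 0.0382 with an estimated correlation. Of 24 complement and phagocytic receptor genes, 10 rose, including C4b by 4.69 ± 0.24 and Cfb by 5.27 ± 0.37 (log2 ± SE), with adjusted p = 0.0254 with an estimated correlation. Adjusted over the list alone, 34 and 11 members rose. These were the 2 lists called with an estimated correlation.

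Of the 33 disease-associated microglia genes tested, 25 rose, and 28 when adjusted over the list alone: Spp1 rose by 6.14 ± 0.60, Cst7 by 4.53 ± 0.31, Axl by 3.77 ± 0.29 and Itgax by 2.85 ± 0.23 (log2 ± SE), with adjusted p = 0.0835 with an estimated correlation. Cytokines and chemokines rose in 17 of 25 cases, with 17 higher and 1 lower when adjusted over the list alone, Ccl12 by 4.98 ± 0.34 and Ccl2 by 3.47 ± 0.28 (log2 ± SE), with adjusted p = 0.0833 with an estimated correlation. MHC class I genes rose in 12 of 14 cases under either adjustment, H2-D1 by 2.76 ± 0.27 and H2-K1 by 2.57 ± 0.26, with adjusted p = 0.0904 with an estimated correlation. Cell cycle genes rose in 17 of 18 cases under either adjustment, including Mcm6 by 2.30 ± 0.32 and Ube2c by 4.26 ± 0.68 (log2 ± SE), and oxidative phosphorylation genes in 29 of 36, or 31 when adjusted over the list alone, including Cox7a2 by 2.51 ± 0.23. With an estimated correlation both of these lists had adjusted p = 0.316. Of the 30 cell cycle genes listed 18 were tested here, against 9 in the age comparison, which holds the same PBS libraries. A gene low in PBS could pass the count filter through the CBE libraries alone. The share of 17 in 18 and the median of this list may therefore be raised by the filter. The same can hold for the disease-associated list, with 33 genes tested here against 26 in the age comparison. It can also hold for cytokines and chemokines, with 25 against 19, and for the interferon list, with 35 against 30. CBE replicate 1 stood apart from the other CBE libraries: chi-square per degree of freedom was 13.5 and 16.1 for its pairs with replicates 2 and 3, and 3.62 between those. The proliferation gene Mki67, chosen after its values were seen, had 18.5, 4.44 and 1.34 CPM in CBE replicates 1, 2 and 3, and 0 counts in each PBS library. Without CBE replicate 1, a step taken for the lists only after seeing the data, 15 of 18 cell cycle genes rose, with a median of 2.07 in place of 2.91 on the log2 scale, and 27 of 36 oxidative phosphorylation genes. Ribosomal proteins rose in 40 of 72 cases, with 55 higher and 1 lower when adjusted over the list alone and adjusted p = 0.334 with an estimated correlation.

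Homeostatic genes fell in 9 of 25 cases, and in 13 when adjusted over the list alone; Slc2a5 fell by 1.52 ± 0.25, Lrba by 1.47 ± 0.23 and Tgfbr1 by 1.15 ± 0.23 on the log2 scale (SE), with adjusted p = 0.316 with an estimated correlation. Among 57 lysosomal genes 14 rose and 3 fell, or 16 and 3 when adjusted over the list alone; Cd63 rose by 1.77 ± 0.27 and the protease Ctsz by 1.39 ± 0.25 (log2 ± SE), with adjusted p = 0.316 with an estimated correlation. Markers of other myeloid cells also moved: 3 of 5 monocyte markers rose, Plac8 by 5.30 ± 1.30 (log2 ± SE), and 1 of 5 neutrophil markers, S100a8, rose by 4.62 ± 1.03, with 4 higher when adjusted over the list alone; without CBE replicate 1 none of the 5 neutrophil markers was called in edgeR. With an estimated correlation these lists had adjusted p = 0.285 and adjusted p = 0.343. Of 13 monocyte and 12 neutrophil markers listed 5 each were tested here, against 1 and 2 in the age comparison. The count filter may therefore raise these shares as well. Of 8 MHC class II genes 2 rose, Cd74 by 2.02 ± 0.29 and H2-Ab1 by 1.74 ± 0.34, with adjusted p = 0.316 with an estimated correlation.

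Of 17 glycolysis and hypoxia genes 7 rose and 1 fell, or 9 and 1 when adjusted over the list alone, with adjusted p = 0.318 with an estimated correlation. Under either adjustment 5 of 16 lipid efflux and storage genes rose and 2 fell, and 4 of 28 glycosphingolipid and ceramide genes rose. None of 15 cholesterol synthesis and 24 immediate early genes was called by edgeR, with 2 and 5 at an unadjusted p under 0.05 and 0 and 3 by DESeq2. Without CBE replicate 1, 2 immediate early genes, Rgs1 and Nfkbiz, rose in edgeR, and their median moved from -0.57 to -0.19. Of 4 markers of border-associated macrophages 2 rose, with 1 lower when adjusted over the list alone, with adjusted p = 0.316 with an estimated correlation, and the 1 endothelial marker tested fell. Markers of B cells, neurons and erythroid cells (1 gene tested each), astrocytes (2) and oligodendrocytes (4) were not called by edgeR or by DESeq2, with 0 at an unadjusted p under 0.05. The astrocyte median and mean were above 0 where camera gave the lower direction.

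The edgeR test called 1388 of 7871 genes, 907 higher and 481 lower, and 812 differed at least 2-fold. The libraries did not overlap in 3088 of the 7871 tested genes, or 39.2%, where chance gives 10% for 3 libraries against 3; 1382 of the 1388 were among them. The count was 748, 644 and 795 without PBS replicates 1, 2 and 3. CBE replicate 3 held 61 counts of Xist and none of Eif2s3y and Kdm5d, and the other acute libraries at most 2 counts of Xist. With library size alone in place of TMM the split turned to 673 higher among 1606 called, 41.9% against 65.3%, as the median log2 fold change of all genes moved to -0.22; changes here are relative to the TMM scale.

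**Figure D2:**
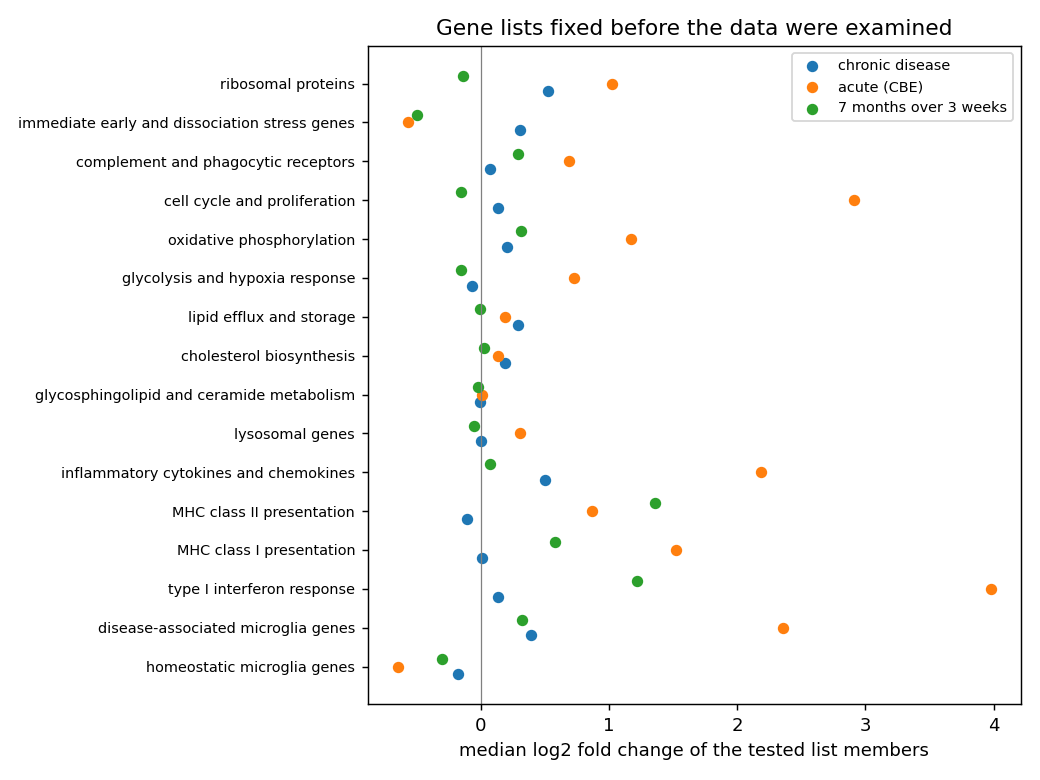
Median log2 fold change (linear axis) of the tested members of each gene list other than the cell type markers, a point each for the chronic, acute and age comparisons. The tested members can differ between comparisons, as with 9, 18 and 9 cell cycle genes, so the points of a list are not always over the same genes. The interferon list stands at 3.98 in the acute and at 0.14 in the chronic comparison.

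Whether both models changed the same genes was tested over the 7041 genes tested in each. Genes higher in both numbered 62, against 14.3 for independent lists, and genes lower in both 24, against 6.25 (one-sided Fisher exact test, p = 2.94e-26 and p = 5.82e-09; adjusted over 4 tests, 1.18e-25 and 1.16e-08). Spp1, Apoe, Lilrb4a, Cst7, Axl and Il1b were among those higher in both, and Slc2a5 and Fcrl1 among those lower in both. Of the 62 genes higher in both, 22 were of the ribosomal protein list, whose estimated inter-gene correlation was 0.39 in the chronic and 0.66 in the acute comparison. The Fisher tests take genes as independent, so their p-values can be too small. Another 11 genes rose in chronic and fell in acute disease, against 8.68 for independent lists, and 7 did the opposite, against 10.3 (one-sided Fisher exact test, p = 0.25 and p = 0.902; adjusted, 0.333 and 0.902). Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.29 and a Spearman correlation of 0.24. No library was used in both comparisons.

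**Figure D3:**
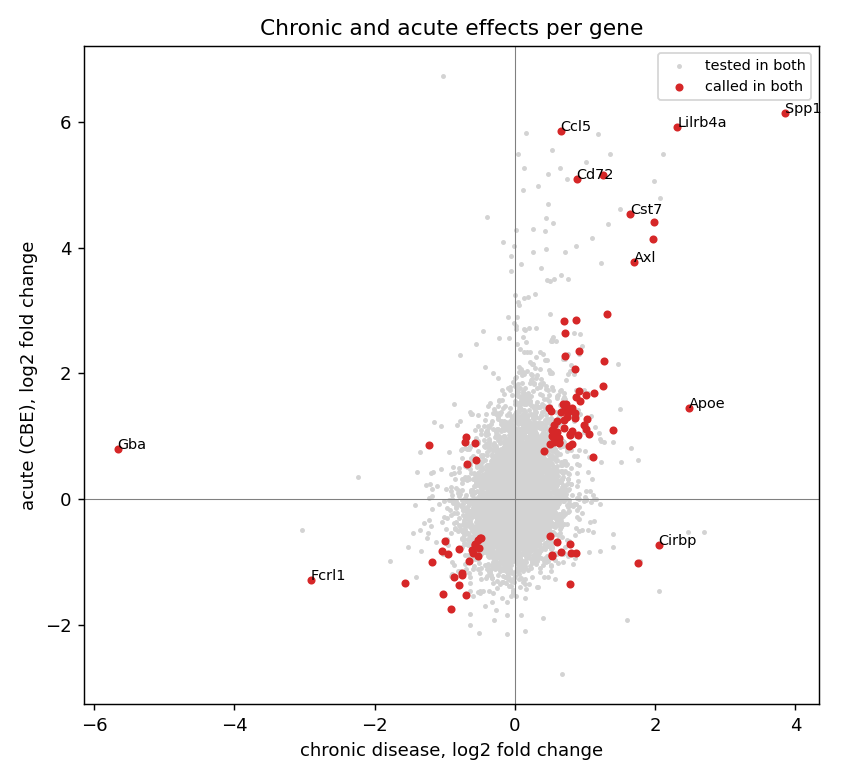
Log2 fold change of each gene tested in both models, chronic on the x axis and acute on the y axis; genes called in both are red. Most of these lie in the quadrants of equal sign, 86 against 18 of opposite sign.

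Whether the effects of both models differed was tested directly. Of 35 interferon response genes 33 had a lower effect in the chronic model, or 34 when adjusted over the list alone (camera adjusted p = 3.54e-86; adjusted p = 9.65e-05 with an estimated correlation). The difference for Oas2 was -7.75 ± 0.58 on the log2 scale (SE; edgeR adjusted p = 2.24e-10). Its baselines were unlike: 1, 2 and 2 counts in PBS replicates 1, 2 and 3, and 7.74 to 34.6 CPM in the 9 controls at 7 months. In the age comparison 21 of 30 interferon response genes were higher at 7 months than in PBS libraries at 3 weeks. Part of the difference in effect may therefore come from the low PBS level. The effect was also lower for 17 of 32 disease-associated microglia genes, 11 of 14 MHC class I genes, 7 of 24 complement and phagocytic receptor genes and 9 of 26 cytokines and chemokines, of which 1 had a higher effect. Adjusted over the list alone these were 23, 12, 10 and 13 genes, with 1 higher in the first list and 1 in the last. With an estimated correlation they had adjusted p = 0.0129, 0.00295, 0.0109 and 0.0129. Cirbp, a cold-induced RNA-binding protein, rose in the chronic and fell in the acute model, with a difference of 2.75 ± 0.30. The fall was called by edgeR and not by DESeq2. Apoe did not pass, with a chronic minus acute difference of 0.99 ± 0.44 (log2 ± SE, edgeR adjusted p = 0.179). Its level was 14530 CPM in CBE replicate 1, the library that stood apart, and 4614 and 5263 in replicates 2 and 3. In PBS libraries it lay between 2626 and 3632. Of 25 homeostatic genes 5 had a higher and 2 a lower effect, or 7 and 2 when adjusted over the list alone, with adjusted p = 0.504 with an estimated correlation. The effect was lower for 18 of 37 oxidative phosphorylation genes (31 over the list alone), 10 of 57 lysosomal (13, with 2 higher), 7 of 15 glycolysis and hypoxia (9, with 1 higher), 4 of 9 cell cycle (7), 3 of 72 ribosomal protein (1) and 2 of 8 MHC class II genes (2). These lists had adjusted p = 0.208, 0.15, 0.0755, 0.177, 0.692 and 0.0755 with an estimated correlation. It was lower for 3 of 29 glycosphingolipid genes and 2 of 15 lipid efflux genes, of which 1 was higher, and higher for 1 of 24 immediate early genes. None of 16 cholesterol synthesis genes was called by edgeR or by DESeq2, with 0 at an unadjusted p under 0.05. Of the cell type markers edgeR called 1 of 4 for border-associated macrophages, lower, and none for monocytes, neutrophils, B cells, astrocytes, oligodendrocytes, neurons and endothelial cells; DESeq2 called none, with 1, 1, 0, 0, 2, 0 and 1 of the latter at an unadjusted p under 0.05. Median, mean and test differed in sign for the glycosphingolipid, lipid efflux and border-associated macrophage lists. Without Gba the mean of the glycosphingolipid list moved from -0.16 to 0.066 and that of the lysosomal list from -0.39 to -0.28.

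The edgeR test called 744 of 8158 genes, 225 with a higher and 519 with a lower effect in the chronic model, or 30.2% higher. With library size alone 59.6% of 832 were higher, as the median of all genes moved to 0.19 on the log2 scale. Age, duration and the way the enzyme was lost differ together between the models.

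Wildtype libraries at 7 months were compared with PBS libraries at 3 weeks. Of 30 interferon response genes 21 were higher at 7 months, 23 when adjusted over the list alone, including Phf11b by 1.91 ± 0.21 (log2 ± SE; edgeR adjusted p = 3.48e-06). MHC class II genes were higher in 4 of 8 cases, Cd74 by 1.86 ± 0.16 and H2-Ab1 by 2.19 ± 0.19, and MHC class I genes in 6 of 14; adjusted over the list alone, 6 class II genes were higher and 1 lower, and 10 class I genes higher. Of 25 homeostatic genes 1, P2ry12, was higher by 0.79 ± 0.16 and 7 were lower, or 1 and 8 when adjusted over the list alone (adjusted p = 0.382 with an estimated correlation). Lyz2 was higher by 1.97 ± 0.19 and C4b by 2.59 ± 0.23. Lower at 7 months were Fcrls, by -1.37 ± 0.14, and Apoe, by -1.19 ± 0.15 (log2 ± SE). With an estimated correlation none of the 25 lists tested passed, with adjusted p = 0.187 for the interferon and both MHC lists.

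Among the largest rises were genes known from hepatocytes: Ttc36 by 5.61 ± 0.48, Apoa2 by 5.89 ± 0.89 and Hp by 5.59 ± 0.98 (log2 ± SE). Of 31 such genes tested, in a list written after the data were seen, 26 were higher at 7 months (adjusted p = 0.0715 with an estimated correlation). Of these genes 40 are listed in the chronic table, and 22 in the acute one. Their summed level without Ttr was 1169 or more CPM in each of the 12 libraries of 7-month mice, 188 in CBE replicate 1, 134 in PBS replicate 3 and at most 21.45 in the other 3-week libraries.

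**Figure D4:**
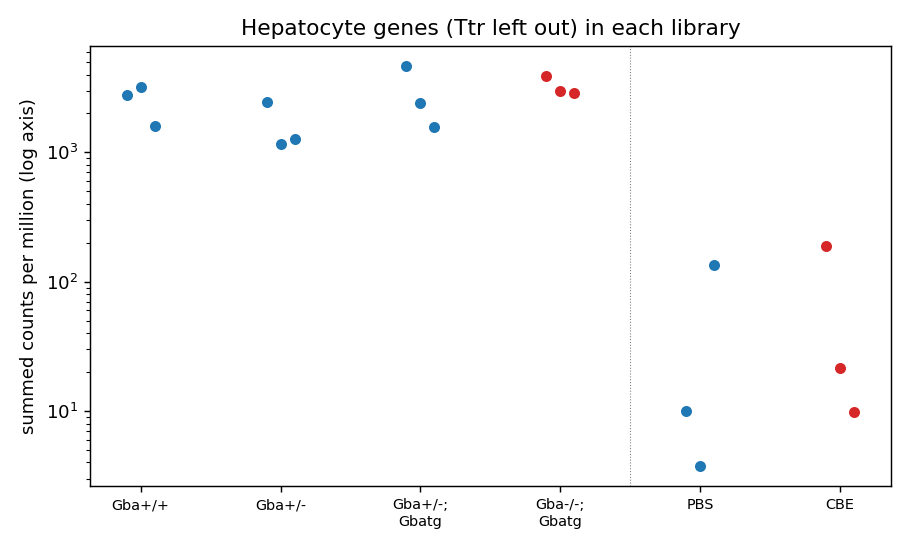
Summed CPM of the hepatocyte gene list, Ttr left out, in each library on a log axis. The 7-month libraries lie between 1169 and 4661, and the 3-week libraries between 3.77 and 188.

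Of 26 disease-associated genes 5 were higher and 3 lower, of 23 complement and phagocytic receptor genes 8 and 2, of 19 cytokines and chemokines 4 and 2, of 56 lysosomal genes 4 and 4, of 36 oxidative phosphorylation genes 5 and 0, of 71 ribosomal proteins 2 and 1, of 15 lipid efflux genes 1 and 3 and of 17 glycolysis genes 0 and 2. Adjusted over the list alone these were 12 and 3, 10 and 4, 6 and 3, 5 and 5, 9 and 0, 0 and 1, 2 and 4, and 0 and 2. None of 28 glycosphingolipid, 14 cholesterol synthesis, 9 cell cycle and 23 immediate early genes was called by edgeR, with 6, 4, 1 and 3 at an unadjusted p under 0.05 and 0, 0, 0 and 1 by DESeq2. The monocyte marker Hp, which the hepatocyte list also holds, and 1 of 2 neutrophil markers were higher, and the B cell and erythroid markers (1 each) and 1 of 2 markers of border-associated macrophages were lower. Markers of astrocytes (2), oligodendrocytes (4), neurons (1) and endothelial cells and pericytes (2) were not called by either tool, with 2, 0, 1 and 2 at an unadjusted p under 0.05. Median, mean and test differed in sign for the glycosphingolipid, lipid efflux and endothelial lists.

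The edgeR test called 919 of 7930 genes, 521 higher and 398 lower at 7 months, and DESeq2 called 575. The libraries did not overlap in 2382 of the 7930 tested genes, or 30.04%, where chance gives 10%; 902 of the 919 were among them. With library size alone 75.4% of 974 genes were higher, against 56.7%, as the median of all genes moved to 0.11 on the log2 scale. With the 3 CBE libraries added to the fit, a setting chosen after seeing the data, the count was 452. Without the hepatocyte list it was 895. The count was 431 without wildtype replicate 1 and 607 without replicate 2. The 2 ages come from separate experiments, so age, treatment with doxycycline or PBS, and batch cannot be told apart here.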

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

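The tests on Fcrls and Fcrl1, Gba, Cirbp and the heat shock genes, the hepatocyte list and Alb were chosen after the results were seen; those on other groupings of the libraries were planned before, except that the draws were parted by the acute split only afterwards, and that on depth was set before its own result was seen.

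The chronic and acute effects differed for 744 genes by a test of the difference itself. Among genes that met the naming rule, the chronic minus acute difference was largest for Mycl at 3.48, Notch4 at 3.47, Slc5a10 at 3.42, Pik3ip1 at 3.20 and Cirbp at 2.75 on the log2 scale, and lowest for Phf11a at -8.21, Oas2 at -7.75, Oas3 at -7.41, Gba at -6.49 and Ifi27l2a at -5.72. When labels were regrouped inside each experiment, 8 of 100 groupings, the real one included, called as many genes, and the highest other called 1042. The 7 others were all among the 12 draws that kept or mirrored the acute split and so still held the CBE effect; these called between 643 and 1042 genes, and the 87 draws that broke it at most 6. The share of 8 in 100 therefore does not show whether chance can be excluded. The 12 draws do not show that the real chronic grouping adds to the count of 744.

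For the chronic comparison, 1 of 100 splits of the 12 libraries, the real one, called as many genes. It called 243 in a 2-group fit, against 15 in the highest other. This argues against chance as the source, and 1 in 100 is the smallest share these splits can give. Every other split puts diseased libraries among the controls, which can widen the spread, so low counts there are partly built in. For comparisons of 3 against 3 the 10 possible splits are too few for a share under 0.05, and in each only 1, the real split, called as many. In fits of 6 libraries the real split called 37 genes against Gba+/-;Gbatg, 155 against Gba+/- and 83 against Gba+/+, and the highest other split 0, 1 and 0. For CBE against PBS and for age the real split called 1388 and 919 genes and the highest other 0. Between control genotypes the real grouping called 0 genes, so all 100 groupings had to call at least as many and the comparison decides nothing; the highest other called 44.

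Fcrls and Fcrl1 fell near the Gba locus. A response to disease as the whole cause would leave the 6 heterozygous control libraries at the Gba+/+ level, while a difference carried with the Gba allele would place them between. They lay below Gba+/+ by -0.68 ± 0.23 for Fcrls and -0.70 ± 0.23 for Fcrl1 (log2 ± SE), with two-sided exact permutation p = 0.0595 and 0.0119 over 84 splits, the second being the smallest these can give, and with edgeR adjusted p = 0.974 and 0.963 over all genes. Both were under 0.05 in edgeR before adjustment, but Fcrls missed that threshold in the exact test, which was added later. The library labelled Gba+/-;Gbatg replicate 3 had 3292 CPM of Fcrls and, at 224.5 CPM, also had Gba within the Gba+/+ range. Fcrls lay between 1492 and 1926 CPM in the other heterozygous libraries and between 2994 and 3247 in the Gba+/+ libraries. Gba itself differed between the 6 heterozygous control libraries and Gba+/+ by -0.71 ± 0.16 (log2 ± SE; edgeR adjusted p = 0.382). A response that follows the Gba level would therefore also place these libraries between, and the test cannot part the explanations. Both explanations stay open, and Fcrl1 also fell under CBE, by 1.28 ± 0.21. A wider effect on the region was not decided: 3 of 122 tested genes within 10 Mb of Gba were called, against 222 of 6810 elsewhere (one-sided Fisher exact test, p = 0.763), and these were Fcrls and Fcrl1, which prompted the test, and S100a10, which rose by 1.03 on the log2 scale.

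Hepatocyte genes stood in all 12 libraries of 7-month mice. Hepatocytes with their usual profile would bring Alb, yet Alb reached at most 11.9% of Apoa1 in these libraries, which argues against them, although a loss of Alb in the counting was not tested. A fixed amount of carried-over RNA would weigh more in shallow libraries; the Spearman correlation of the summed level with total count was -0.20 (permutation p = 0.528) and Pearson's r -0.26 (permutation p = 0.402), or -0.28 without the 2 libraries farthest from the median depth, which decides nothing with 12 libraries. A change with age cannot be told apart from the experiment, although CBE replicate 1 reached 188 CPM at 3 weeks. The purity of the sorted microglia was not tested, and the source stays open.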

How the results depend on the processing

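Scaling by library size alone and the fits without libraries holding Xist, with CBE added or without hepatocyte genes, and the lists without Gba or CBE replicate 1, were chosen after seeing the data. Same-numbered libraries did not deviate together in every pair (correlations from -0.092 to 0.18 in acute, -0.039 to 0.16 in age, -0.11 to 0.21 in chronic), so the numbers name libraries only. With the replicate block the counts were 196 (chronic), 45, 142 and 94 (against Gba+/-;Gbatg, Gba+/- and Gba+/+), 1455 (acute) and 921 (age). Leaving out each library gave 123 to 289 genes in chronic, 29 to 95, 46 to 125 and 37 to 95 against the single controls, 0 to 3 between controls, 644 to 1398 in acute and 431 to 817 in age. DESeq2 called 575 age genes and 1 control gene; no filter gave 2 control genes; CBE added to the age fit gave 452. At least 2-fold left 57 chronic, 812 acute and 376 age genes, and 17 shared genes higher and 4 lower. With an estimated correlation 2 of 8 lists stayed past the threshold in chronic, 2 of 14 in acute, 0 of 6 in age and 5 of 13 in the difference. Gba+/-;Gbatg replicate 2 held 16 counts of Xist and Gba+/- replicate 3 held 20, with 0 of Kdm5d in both. The Gba-/-;Gbatg libraries held 0 counts of Xist. Compared groups may therefore be unbalanced for sex, which was not in the fits. Without these 2 control libraries, the ones with at least 10 Xist counts, 190 chronic genes were called, and without CBE replicate 3, with 61, 1398 acute genes. The cause of these changes was not tested.

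The 201 called values of named genes kept their sign in all 2860 alternatives run, and in 226 they were no longer past the threshold. They were picked as called, the largest changes also for libraries without overlap, so the kept sign says little. The sign changes were in genes not called and, without Gba, in the means of lysosomal genes (0.016 in chronic) and glycosphingolipid genes (0.071 in chronic, 0.066 in the difference). In the chronic comparison the log2 values, as the range over leaving out each library, were H2-DMa -0.0014 to 0.18, Mag -0.19 to 0.24, -0.25 with the replicate block, Slc1a3 -0.23 to 0.078. In the acute comparison the log2 values, as the range over leaving out each library, were Alas2 -0.44 to 0.87, Cnp 0.092 to 0.30, -0.0052 with library size alone, Mbp -1.41 to 1.39, 0.0034 with the replicate block, Mrc1 -0.42 to 0.047, Nrgn -1.30 to 0.30. In the age comparison the log2 values, as the range over leaving out each library, were Cnp -0.13 to 0.13, 0.085 with all 18 libraries in the fit, 0.082 with library size alone, Csf3r -0.026 to 0.20, Rpl13 -0.55 to -0.23, 0.18 with all 18 libraries in the fit, Trf -0.12 to 0.072, 0.075 with library size alone. The all-library age fit mixes countings. On simulated data with the depth and spread of each comparison, 74 (chronic), 45 (acute), 65 (age) and 15 (difference) of 100 genes changed 2-fold were found. Those data had changes balanced in direction and no library that stood apart, and depth was not varied alone. The planned change of pseudocount did not apply to counts.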

Other observations

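The tests in this part were chosen after the results were seen, and 5 gene lists were written for them and for the hepatocyte genes.

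Cirbp, a cold-induced RNA-binding protein, rose from 28.3 ± 8.53 CPM in the 9 controls to 114 ± 18.7 in the 3 Gba-/-;Gbatg libraries (SD), a log2 fold change of 2.05 ± 0.18 (SE; edgeR adjusted p = 1.59e-08), and Hspa4, a chaperone, fell by 1.45 ± 0.29. Rbm3, another cold-induced gene, too low for the edgeR filter, was at least 12.8 CPM in the diseased and at most 9.14 in the control libraries. Of 10 glucocorticoid-induced genes 3 rose, with a median of 1.02 on the log2 scale and p = 0.0534 with an estimated correlation, and 1 of 6 clock-controlled genes rose, with p = 0.0793 with an estimated correlation. DESeq2 called 3 and 0 genes of these 2 lists. Adjusted over the 5 added lists both had adjusted p = 0.0991, as had the heat shock chaperones, of which 2 of 20 fell. The cold-induced list held Cirbp alone among tested genes, so its test decides nothing. In the difference between the models 2 of 8 clock-controlled genes had a higher effect in the chronic model, with adjusted p = 0.02 with an estimated correlation, and 2 of 10 glucocorticoid-induced genes did, with adjusted p = 0.127. Neither the heat shock list, with 4 of 20 lower and adjusted p = 0.127, nor the hepatocyte list, with adjusted p = 0.871, passed there with an estimated correlation. The cold-induced list, Cirbp and Rbm3, had adjusted p = 0.00884. It was written after Cirbp was seen, and the difference for Rbm3 was not called, so this value decides nothing beyond Cirbp.

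An effect of Gba loss common to both models was asked about for Cirbp, Rbm3 and the heat shock chaperones only. Cirbp was among 11 genes that rose in chronic and fell in acute disease, and the others were not examined in this way. Of the 3 items asked about, such an effect is argued against for Cirbp alone. Cirbp fell in CBE libraries by 0.74 ± 0.22, with a difference of 2.75 ± 0.30 between the models (log2 ± SE, edgeR adjusted p = 2.03e-07). DESeq2 called 0 genes of the cold-induced list in the acute comparison, so the fall under CBE was an edgeR call only, and it called 1 in the difference. Rbm3 had 30.1, 16.3 and 7.57 CPM in CBE and 8.30, 7.55 and 7.39 in PBS libraries, a log2 fold change of 1.16 ± 0.46 (SE; edgeR adjusted p = 0.103) that passed when adjusted over the list alone. The chronic minus acute difference was 0.58 ± 0.59 for Rbm3 (log2 ± SE; edgeR adjusted p = 0.606), with a median of -0.86 for the heat shock chaperones (adjusted p = 0.127 with an estimated correlation), so a common effect stays open for both. A lower temperature of mice or tissue in the chronic group may account for the pattern. Hspa4, Hspa8, Hsp90ab1 and Hsph1 were set aside, since their values had been looked at. Of the remaining 16 chaperones 14 had negative values, with a median of -0.37 on the log2 scale, but camera p = 0.109 with an estimated correlation does not decide. Their list was written after the whole fit was seen, and the immediate early list already held heat shock genes. These 16 are therefore no independent check. Handling or time of collection cannot be told apart from genotype here, since no label gives a day.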
